A study of Mus musculus with 15 samples.

How the data were processed

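Gene expression was measured by RNA sequencing of colon from C57BL/6 mice in 15 libraries, 5 from untreated controls, 5 from the AOM/DSS model and 5 from model animals given the treatment labelled WMW-H. Polyadenylated RNA was selected, fragmented and made into libraries with the NEBNext Ultra kit, and sequenced on a NovaSeq 6000, per the labels' protocols. The submitters' processing notes name fastp 0.18.0, Bowtie2 2.2.8, HISAT2, StringTie 1.3.1 and RSEM without their order or settings. The genome build and annotation were not given in the sources used here, so no coordinates are printed.

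The authors deposited 1 table of FPKM values (fragments per kilobase of transcript, scaled to library depth), with an Ensembl identifier and a symbol for each of 22063 genes. Of these, 3664 were listed at 0 in all libraries and 51 rows repeated a symbol. In GENCODE release M21, 21973 of the identifiers were found, 21573 of them as protein coding genes. The library totals ran from 507895 to 535410 FPKM, so the values had not been rescaled to a common total.

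Depth was read from the low values, because an FPKM built from whole fragments moves in steps set by transcript length and depth. A range of depths was scanned per library over 3325 genes with 1 annotated transcript of 800 to 6000 nucleotides. With full transcript lengths, the depths were 16300000 to 21200000 fragments. At those depths, 89.3% of 5089 low values came within 0.1 of a whole fragment, where 20% would by chance at a depth not chosen to fit them. On simulated libraries of known depth, the largest error was 0.06%. Multi-transcript genes did not allow whole fragments to be recovered, so no count model was used.

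Genes with at least 1 FPKM in at least 5 libraries were tested, which left 12917. A gene near 0 in 1 group passes only through libraries of the others, so its direction is partly fixed by the filter. Values were transformed to log2(FPKM + 1) and fitted with limma 3.58.1 in R 4.3.3, with a mean per group, all 15 libraries in 1 fit and empirical Bayes moderation with a trend. The 3 comparisons were model versus control, WMW-H versus model and WMW-H versus control, each two-sided with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. In simulated data with the depths found here, the model versus control step on 12870 genes recovered 50 of 50 genes changed 2-fold and 38 of 50 changed 1.25-fold, with 9 false calls among 194. The WMW-H versus model step on 12855 genes recovered 50 and 35 of 50, with 7 false calls among 190. The WMW-H versus control step on 12862 genes recovered 49 and 35 of 50, with 12 false calls among 194.

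For gene lists, 40 lists of pathways and cell types were fixed before the data were examined, as were the tests and all but 1 of the alternatives. Some of the lists were fixed as checks for other tissue, handling, RNA quality or time of day. They were the adipocyte, squamous epithelium, circadian clock, immediate early and heat shock, mitochondrially encoded and ribosomal protein lists. The 39 with at least 5 tested members were compared with all other genes by camera in limma, with a preset inter-gene correlation of 0.01 and, as an alternative, an estimated correlation. The self-contained test fry asked whether the genes of a list moved on balance in 1 direction. In the simulations, camera called the list raised 2-fold in each of the 3 comparisons and 0 of 99 random lists. The simulated genes were drawn independently of each other, so this did not test the preset correlation or the size of camera's p-values. Other splits of the real libraries called a median of 10, 4 and 7 lists in model versus control, WMW-H versus model and WMW-H versus control. List means were compared by exact permutation of 5 against 5 libraries, for which 0.0079 is the smallest two-sided p. The median of all genes was 0.12 in model versus control, -0.07 in WMW-H versus model and 0.05 in WMW-H versus control, and list medians are given relative to it.

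Genes were named by a rule fixed at the same time. It took the 10 largest rises and 10 largest falls per comparison among called genes whose groups did not overlap, without unnamed models, pseudogenes and variable segments of antigen receptors. It added Ido1 and 9 other genes of the kynurenine and AHR pathways, and up to 4 members of each list described, those with the smallest p, plus called members going against the list. Some genes that the rule takes are not reported here. Lists of male accessory gland, pancreas and Paneth cell genes were written after the largest changes of a preliminary fit had been seen, and a list of small-intestinal enterocyte genes was added as a test for the last of these. Figures were drawn with matplotlib 3.10.9.

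The labels call the libraries replicates and do not say that they came from separate animals. The p-values therefore measure only the spread between these libraries, which may be technical. Replicates of each group differed by more than sampling noise, which does not show that they came from separate animals. Each library was counted once, and n = 5 is a number of libraries. The alternatives tried were other pseudocounts, filters and scalings, fits of 2 groups, the replicate number as a block, library weights, robust moderation, an exact rank test, a fold threshold, and leaving out each library in turn. A fit without pancreas and accessory gland genes was added after the data were seen. It left out only the genes of those lists, not other transcripts of these organs.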

Results

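RNA of the colon was compared between untreated mice, mice in which azoxymethane (AOM, a carcinogen) and dextran sulfate sodium (DSS, which injures the colon epithelium) were used to induce colorectal tumours, and such mice given WMW-H. The series concerns Wumei Wan, a herbal formula, and the axis from IDO1 through kynurenine to the aryl hydrocarbon receptor (AHR). The labels give colon as the tissue and colon epithelial cells as the cell type, and the protocols seen here describe no isolation step, so whether other cells were meant to be present is not known. The dose and the meaning of "-H" were not given in the sources used here. Each group had 5 libraries of 16300000 to 21200000 fragments, with 16377 to 16692 genes above 0.

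The groups were far apart and the libraries within a group close together. Correlations of log2(FPKM + 1) over the tested genes ran from 0.992 to 0.995 within groups, and from 0.939 to 0.942 between control and model. WMW-H lay between 0.959 and 0.963 with model and between 0.969 and 0.972 with control. The first principal component held 64.2% of the variance and placed WMW-H between the other groups, and the second, with 22% of the variance, set WMW-H apart from both. WMW-H replicate 3 stood apart on the next component, at -16.66, where the other libraries lay between -1.56 and 5.72.

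**Figure D1:**
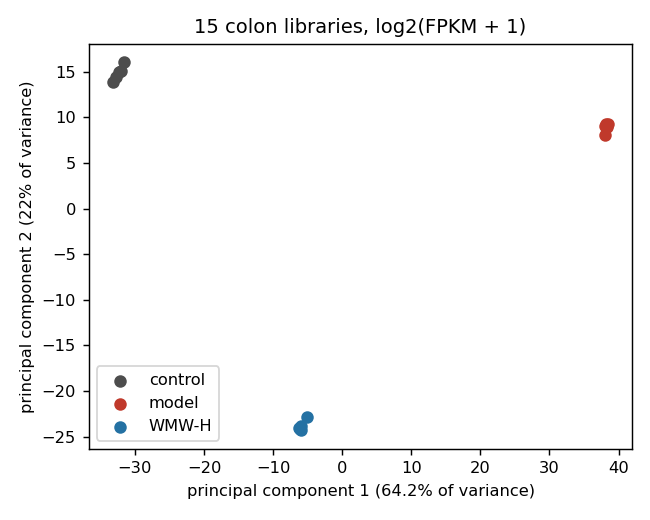
Principal components of log2(FPKM + 1) for the 15 libraries, 1 point per library, coloured by group, with the share of variance on each axis. Control libraries lie at -33.11 to -31.56 on component 1, WMW-H libraries at -6.22 to -5.11 and model libraries at 38.06 to 38.43.

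The first question was whether transcripts of the IDO1, kynurenine and AHR genes differed between groups. Ido1 (ENSMUSG00000031551), whose product opens tryptophan's breakdown to kynurenine, was highest in control at 9.30 ± 0.69 FPKM (SD, n = 5). It was 3.33 ± 0.72 FPKM in model and 6.84 ± 0.63 FPKM in WMW-H. Ido1 thus fell in model against control by 1.27 on the log2 scale (SE 0.10, limma adjusted p = 5.27e-09), and rose in WMW-H against model by 0.87 (adjusted p = 6.98e-07), with no overlap of the groups. It stayed below control in WMW-H, with a log2 change of -0.40 (adjusted p = 0.00241).

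Ahr (ENSMUSG00000019256), the receptor for kynurenine and other ligands, was at 3.78 ± 0.23 FPKM in control, 4.51 ± 0.11 in model and 4.15 ± 0.48 in WMW-H. Its log2 change of 0.20 in model against control passed over all genes (limma adjusted p = 0.0078) but not with median-of-ratios size factors (adjusted p = 0.134) or quantile normalization (adjusted p = 0.449), over alternatives from 0.00282 to 0.449. Its changes in WMW-H, -0.10 against model (adjusted p = 0.156) and 0.10 against control (adjusted p = 0.164), did not pass; the latter passed without WMW-H replicate 3 (adjusted p = 0.0383; range over alternatives 0.0383 to 0.742). Tiparp (ENSMUSG00000034640), a target gene of AHR, was at 5.05 ± 0.45, 3.21 ± 0.38 and 4.27 ± 0.29 FPKM in control, model and WMW-H. It fell in model by 0.52 (adjusted p = 4.35e-06) and rose in WMW-H against model by 0.33 (adjusted p = 0.000528). Its change of -0.20 in WMW-H against control (adjusted p = 0.0227) was lost in the exact rank test (adjusted p = 0.0581), without control replicate 2 (0.0583) or 3 (0.0598) and without WMW-H replicate 4 (0.0518), over alternatives from 0.00214 to 0.0598. Nqo1, another AHR target, fell in model by 0.34 and rose in WMW-H against model by 0.64 (adjusted p = 8.32e-10), from 23.0 ± 0.72 to 36.5 ± 1.77 FPKM.

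Tdo2, Kmo, Kynu, Haao, Ahrr, Cyp1a1 and Cyp1b1 lay under 1 FPKM on average in each group and were not tested. Cyp1a1, the classical AHR target, was at 0.32 ± 0.12 FPKM in control, 0.15 ± 0.06 in model and 0.23 ± 0.08 in WMW-H. Of the same list, Ahrr was at 0.36 ± 0.09, 0.33 ± 0.12 and 0.72 ± 0.08 FPKM in control, model and WMW-H. Cyp1b1 was at 0.27 ± 0.06, 0.18 ± 0.09 and 0.39 ± 0.14 FPKM in these groups. Over both lists, 13 genes were tested: 4 rose and 6 fell in model, 6 rose and 4 fell in WMW-H against model, and 2 rose and 7 fell in WMW-H against control. In WMW-H against model the lists parted, with 4 AHR list genes higher and 0 lower. In the kynurenine list 2 rose, Ido1 among them, and 4 fell, including Kyat1 by 0.635, Slc7a5 by 0.434 and Wars1 by 0.153. Adjusted over the list alone, the counts were equal. As sets, neither differed from other genes in model versus control (camera adjusted p = 0.294 for the kynurenine pathway and 0.0592 for AHR and its targets) or in WMW-H versus model (0.739 and 0.072). The last of these passed in 1 of 23 alternative settings, with TPM (adjusted p = 0.032). In WMW-H versus control, the kynurenine list was lower (adjusted p = 0.0266; adjusted p = 0.0566 with an estimated correlation), with Wars1, Il4i1, Ido1, Slc7a5 and Kyat1 down, and the AHR list was not called (0.906). List means by exact permutation gave the smallest p, 0.00794, for both lists in model versus control, with mean log2 changes of -0.19 for the kynurenine pathway and -0.18 for AHR and its targets. The first mean rested on few genes: of 7 tested, 2 rose and 3 fell, with Ido1 at -1.27 and Kyat3 at -0.65, and the median was -0.02. For WMW-H versus model the mean log2 changes were -0.04 (permutation p = 0.27) and 0.25 (permutation p = 0.00794). For WMW-H versus control they were -0.23 (permutation p = 0.00794) and 0.07 (permutation p = 0.0714). In each comparison, most of the other lists fixed beforehand also reached a permutation p of 0.00794. In model versus control these included the cell cycle list, which camera did not call (adjusted p = 0.711). Reaching the smallest p therefore does not set the kynurenine or AHR list apart from other lists.

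**Figure D2:**
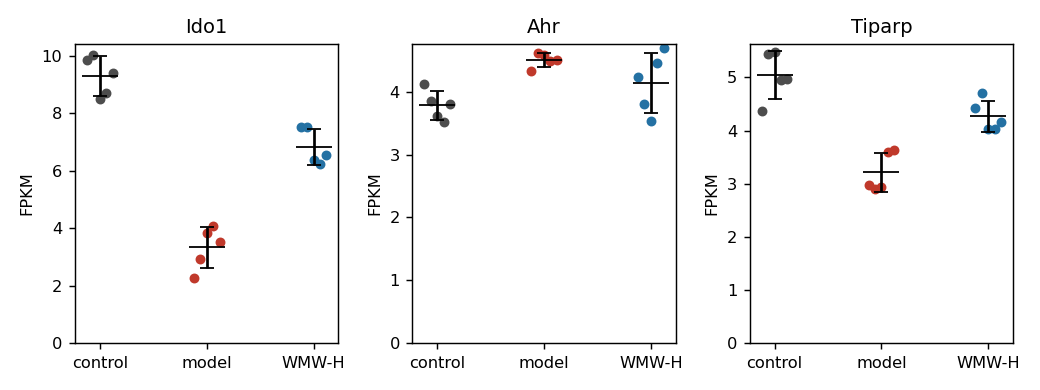
FPKM of Ido1, Ahr and Tiparp in each library (points), with the group mean and SD (bars), for 5 control, 5 model and 5 WMW-H libraries. Ido1 averaged 9.30, 3.33 and 6.84 FPKM in control, model and WMW-H.

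The model was then compared with control, which asks what AOM/DSS changed in the colon. Targets of Wnt signalling, the pathway whose activation drives most colorectal tumours, rose together, along with neutrophil, mast cell and inflammatory cytokine genes. Interferon-stimulated genes, MHC class II genes and markers of goblet cells and cytotoxic lymphocytes fell. At least 2-fold changes were called in 537 genes that were higher and 247 that were lower in model. Without a fold limit, 5881 genes were higher and 2658 lower at an adjusted p under 0.05, with a median change of 1.26-fold, and the 5 libraries of each group did not overlap for 52.9% of genes (0.79% by chance). The split between directions depended on scaling: 68.9% of calls were higher as deposited, 73.6% with TPM, 51.3% with median-of-ratios size factors and 47.5% after quantile normalization.

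All 22 Wnt targets rose, with a median 1.56 above that of all genes on the log2 scale (camera adjusted p = 8.83e-13). Mmp7, a matrix protease, went from 1.92 ± 0.21 to 155 ± 6.42 FPKM, and Notum, a secreted Wnt antagonist, from 0.157 ± 0.041 to 47.4 ± 1.82 FPKM. Nkd1 went from 6.30 ± 0.44 to 139 ± 2.15 FPKM and Apcdd1 from 2.15 ± 0.18 to 46.2 ± 1.91 FPKM. Of 10 fetal-like and regenerating epithelium genes, 9 rose (camera adjusted p = 0.00162). Clu rose from 58.5 ± 2.40 to 159 ± 3.88 FPKM, while Ly6a fell by 0.14, a call lost with TPM (adjusted p = 0.0525) and after quantile normalization (0.114), over alternatives from 4.16e-06. The 25 cell cycle genes were not called as a set (adjusted p = 0.711), with 10 higher and 4 lower.

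Among inflammatory cytokines, 10 of 11 tested genes, of 18 listed, rose (relative median 1.63, camera adjusted p = 0.000172). Il1b rose from 1.26 ± 0.30 to 10.3 ± 0.78 FPKM, and Cxcl5, a chemokine that attracts neutrophils, from 0.111 ± 0.097 to 23.3 ± 0.73 FPKM. All 6 tested neutrophil genes, of 13 listed, rose (adjusted p = 0.00127): S100a9 went from 0.154 ± 0.22 to 19.3 ± 1.57 FPKM, and S100a8 was listed at 0 in all control libraries and at 11.6 ± 2.48 FPKM in model. Genes this low in control passed the filter through other groups, so their rise was partly fixed by it. All 7 mast cell genes rose (adjusted p = 9.97e-05), such as the mast cell protease Mcpt1 from 4.46 ± 0.72 to 49.1 ± 2.11 FPKM. Macrophage and monocyte genes were higher, 12 of 14 (adjusted p = 0.0132; adjusted p = 0.0591 with an estimated correlation). The fibroblast and matrix list rose as well, with 12 genes up and 3 down of 15 (adjusted p = 0.00179). Fn1 rose from 36.8 ± 0.33 to 110 ± 1.90 FPKM and Col1a1 by 1.34 on the log2 scale, while Postn fell by 0.66 and Lum by 0.38.

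All 14 type I interferon response genes fell (relative median -1.94, camera adjusted p = 6.12e-17). Isg15 fell from 84.7 ± 1.82 to 11.6 ± 1.20 FPKM, Ifit1 from 39.8 ± 1.37 to 4.38 ± 0.68 FPKM and Oasl2 from 152 ± 6.08 to 25.2 ± 1.298 FPKM. In the interferon gamma list, 15 of 17 genes fell (relative median -1.32, adjusted p = 2.53e-13), among them the GTPases Igtp and Irgm1, by 2.10 and 1.88, and the peptide transporter Tap1, by 1.65, while Ubd rose by 0.69. Of 10 MHC class II genes, which present antigen to T helper cells, 7 fell (relative median -1.11, adjusted p = 1.32e-07), such as Cd74 from 1047 ± 12.1 to 491 ± 7.24 FPKM and H2-Aa from 418 ± 6.74 to 170 ± 5.79 FPKM. All 6 cytotoxic lymphocyte genes fell (adjusted p = 3.6e-05), Gzma from 9.29 ± 0.74 to 1.26 ± 0.33 FPKM and Ccl5 from 29.9 ± 1.83 to 7.05 ± 0.61 FPKM.

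Goblet cell genes fell in 11 of 12 cases (relative median -0.75, camera adjusted p = 1.23e-08), with Clca1 down from 3102 ± 44.3 to 1174 ± 13.1 FPKM and the transcription factor Spdef from 129 ± 5.11 to 53.5 ± 1.296 FPKM. Tff3 went against them, from 677 ± 34.9 to 918 ± 37.0 FPKM. Klk1 and Zg16 of this list are also made by the pancreas, whose genes fell in the same comparison. Of 18 absorptive colonocyte genes, 13 fell and 4 rose (adjusted p = 5.35e-05): Guca2a fell by 0.92 and the sodium and proton exchanger Slc9a3 by 0.66, while Atp12a rose by 2.54 and Slc37a2 by 2.62. Also lower as sets were enteroendocrine (8 of 11 genes, adjusted p = 8.86e-05), tuft cell (5 of 6, 0.00949), T cell (6 of 12, 0.0215), enteric neuron and glia (9 of 12, 6.98e-05), adipocyte (8 of 9, 8.99e-05), xenobiotic and steroid metabolism (10 of 14, 5.35e-05) and circadian clock genes (8 of 12, 0.00179). Gcg, Sst, Chga, Chgb and Scg2 of the enteroendocrine list, all lower, are also made by pancreatic islets, and pancreatic genes fell in the same comparison. The T cell call was lost in 2 of 23 alternative settings, with adjusted p from 0.0119 to 0.0663 over them.

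Also higher as sets were tight junction (11 of 16 genes, camera adjusted p = 0.0132), endothelium (9 of 11, 0.0259), squamous epithelium (5 of 5 tested, of 10 listed, 0.000743) and immediate early and heat shock genes (11 of 13, 0.00186). The squamous epithelium genes averaged 0.084 in control on the log2(FPKM + 1) scale. They passed the filter through other groups, so their direction was largely fixed by it. All lists set as checks for other tissue, handling, RNA quality or time of day were called in this comparison. Such differences between groups cannot be told apart from AOM/DSS here. Calls lost with an estimated correlation were myeloid suppression (6 of 7 higher; adjusted p = 0.0926 with an estimated correlation), glycolysis and hypoxia (12 of 17 higher; adjusted p = 0.145 with an estimated correlation) and ribosomal proteins (13 of 15 higher; adjusted p = 0.341 with an estimated correlation). The nuclear oxidative phosphorylation call (10 of 14 lower; adjusted p = 0.113 with an estimated correlation) and the mitochondrially encoded call (3 of 13 lower; adjusted p = 0.538 with an estimated correlation) were lost too, and the latter's median turned positive under 2 of 3 scalings and its call was kept in 16 of 23 alternative settings. Epithelial antimicrobial defence (0.711), plasma cell (0.0513), B cell (0.315), regulatory T cell and checkpoint (0.419), smooth muscle (0.442), fatty acid oxidation (0.481) and p53 target genes (0.294) were not called. Of these, the plasma cell list passed in 8 of 23 alternative settings (adjusted p from 0.0377 to 0.467). In all, camera called 14 lists higher and 15 lower, of which 23 kept their call with an estimated correlation. Counts of called members were equal when adjusted over the list alone for 37 of 40 lists. The exceptions were enteric neuron and glia (10 lower), xenobiotic and steroid metabolism (11 lower) and mitochondrially encoded genes (2 lower). With size factors, the tight junction (adjusted p = 0.0502) and ribosomal protein calls (0.147) were lost, and with TPM the myeloid suppression call (0.0575). The dendritic cell list had 3 tested genes, too few for camera, and all rose.

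**Figure D3:**
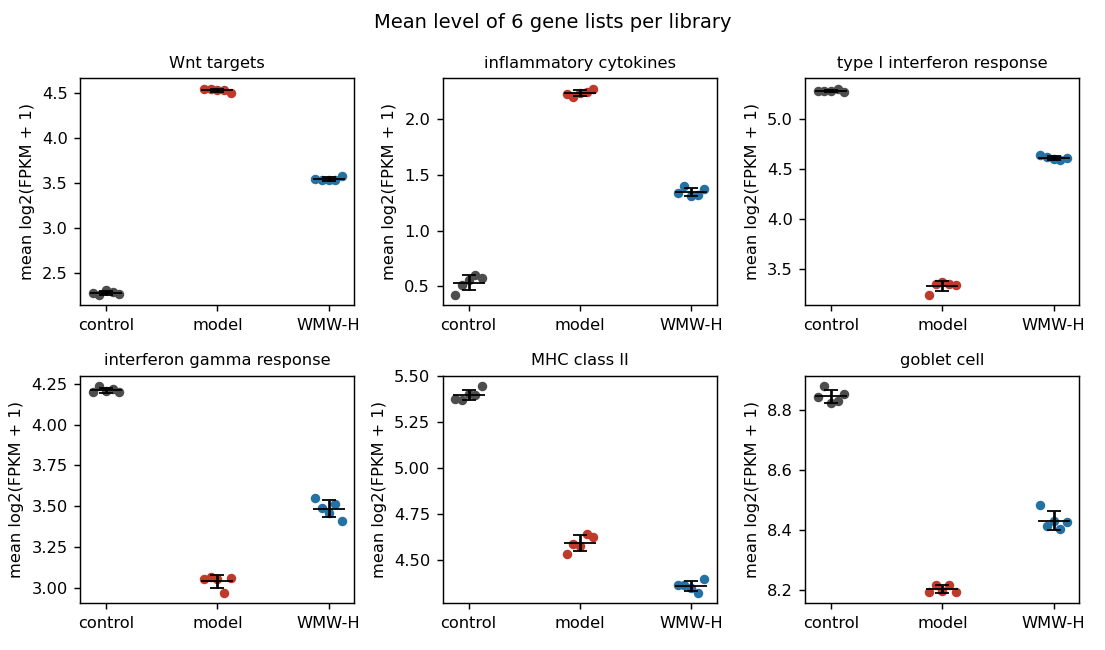
Mean log2(FPKM + 1) of 6 gene lists in each library (points), with the group mean and SD (bars); the axes do not start at 0. Median changes in model versus control, relative to all genes, were 1.56 for Wnt targets and -1.94 for type I interferon response genes.

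The largest rises in model were genes known from other organs. Svs5 and Svs4, secretory proteins of the seminal vesicle, were at 1113 ± 19.8 and 867 ± 26.3 FPKM in model, against 0.818 ± 0.52 and 0.537 ± 0.50 in control. Of 15 male accessory gland genes, 13 were tested and all rose; together they made 0.59% ± 0.011 of the FPKM total in model, 4e-04% in control and 6e-04% in WMW-H. Svs6, Semg1, Aoc1l3, Svs3a and Svs3b, all in the gland list, were also among the 10 largest rises. The other 3 were Paneth cell defensins, Defa24, Defa33 and Defa3, antimicrobial peptides of the small-intestinal crypt. The 17 Paneth cell genes all rose, to 0.293% ± 0.0092 of the total from 0.0022%, and were at 0.0776% ± 0.0031 in WMW-H; single defensins share reads with near-identical copies. Lyz1, which is outside the defensin family, was at 5.41 ± 0.72, 444 ± 6.18 and 205 ± 3.17 FPKM in control, model and WMW-H.

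Pancreatic genes moved with the groups as well. They made 6.97% ± 0.031 of the FPKM total in control, 1.59% ± 0.014 in model and 3.29% ± 0.071 in WMW-H, and in model 36 of 36 tested genes fell. The labels do not say whether pancreas was collected with the colon, so the tissue these transcripts came from is not known. Ctrb1, a digestive protease precursor chosen after its values were seen, was at 6460 ± 103, 1306 ± 15.4 and 2569 ± 128 FPKM in the 3 groups. The insulin gene Ins2 was at 5.56 ± 0.97 FPKM in control, listed at 0 in all model libraries and at 0.762 ± 0.38 FPKM in WMW-H. The largest falls in model were Mptx1, from 2332 ± 27.4 to 187 ± 6.70 FPKM, and Pla2g4c, from 60.0 ± 1.27 to 5.37 ± 0.20 FPKM. The immunoglobulin light chain gene Iglc1 fell from 582 ± 34.99 to 61.9 ± 3.99 FPKM. The others were the interferon-inducible genes Ifit1, Ddx60 and Iigp1, the apolipoprotein L genes Apol9a and Apol9b, and the pancreatic amylases Amy2a5 and Amy2a3, which share reads.

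**Figure D4:**
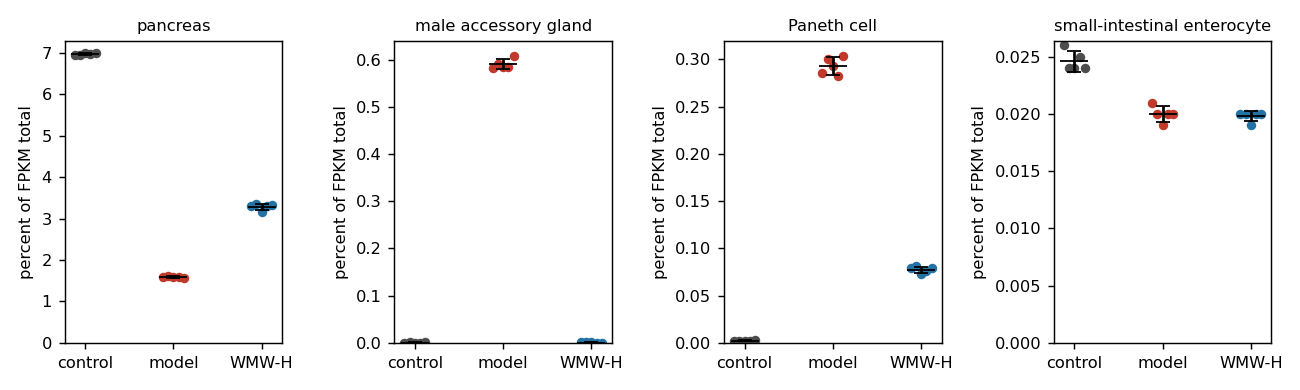
Share of each library's FPKM total, in percent, taken by pancreas, male accessory gland, Paneth cell and small-intestinal enterocyte genes (points, 1 per library), with group means and SD (bars). Pancreatic genes take 6.97% in control, 1.59% in model and 3.29% in WMW-H.

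WMW-H was compared with model to ask what the treatment changed. Type I interferon genes, which were low in model, rose, and Wnt targets and inflammatory cytokines, which were high, fell. At least 2-fold changes were called in 108 genes that were higher and 249 that were lower in WMW-H. Without a fold limit, 3347 genes were higher and 5286 lower, with a median change of 1.26-fold, and groups did not overlap for 51.2% of genes (0.79% by chance). Higher genes made 38.8% of calls as deposited, 49.6% after quantile normalization, 32.7% with TPM and 34.1% without pancreas and accessory gland genes.

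All 14 type I interferon response genes rose (relative median 1.48, camera adjusted p = 1.22e-11). Isg15 reached 57.1 ± 2.55 FPKM, a log2 change of 2.21, and Ifit1 rose by 2.36, to 26.4 ± 1.01 FPKM. Oasl2 rose by 1.39 and Ifit3 by 1.73. In the interferon gamma list, 13 of 17 genes rose (adjusted p = 6.73e-06), among them Irgm1 by 1.16 and Igtp by 0.88, while Ubd fell by 1.304. MHC class II genes were not called as a set (adjusted p = 0.313), with 6 lower and 0 higher of 10.

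Of 22 Wnt targets, 20 fell (relative median -0.94, camera adjusted p = 1.71e-08). Notum fell to 14.1 ± 0.93 FPKM, Nkd1 to 43.6 ± 1.71 FPKM and Apcdd1 to 13.6 ± 0.80 FPKM, each by at least 1.65 on the log2 scale, and Sp5 fell by 2.06. Inflammatory cytokine genes fell in 10 of 11 cases (relative median -0.78, adjusted p = 0.00197), with Cxcl5 down to 7.61 ± 0.60 FPKM, Cxcl2 from 5.47 ± 1.05 to 0.840 ± 0.21 FPKM and Tnf from 5.80 ± 0.43 to 2.02 ± 0.49 FPKM. Immediate early and heat shock genes fell in 12 of 13 cases (adjusted p = 3.39e-05), Hspa1b by 1.81 and Hspa1a by 1.64, near-identical copies that share reads, and Junb by 0.63. This list and the adipocyte, mitochondrially encoded and squamous epithelium lists were set as checks for other tissue, handling or RNA quality. All of these were called here, and such differences cannot be told apart from the treatment. The circadian clock (camera adjusted p = 0.707) and ribosomal protein lists (0.461), also set as checks, were not called. All 9 adipocyte genes fell (adjusted p = 0.00281), such as Plin1 from 8.88 ± 0.93 to 4.09 ± 0.24 FPKM. All 7 B cell genes fell (adjusted p = 0.0203; adjusted p = 0.0846 with an estimated correlation), Cd79a from 15.04 ± 1.12 to 7.59 ± 0.59 FPKM.

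Goblet cell genes rose in 8 of 12 cases (relative median 0.38, camera adjusted p = 0.00149). Agr2 rose by 0.70 and Clca1 by 0.61, to 1793 ± 32.1 FPKM, while Fcgbp fell by 0.40. Pancreatic genes, made by an organ that also expresses Klk1 and Zg16 of the goblet list, were higher in 34 of 36 cases. Enteroendocrine genes rose in 9 of 11 cases (adjusted p = 0.000112), Gcg, which encodes glucagon and GLP-1, from 34.97 ± 1.74 to 67.4 ± 3.28 FPKM, while Pyy fell by 0.20, a call lost in the exact rank test (adjusted p = 0.0509; from 3.21e-05 over alternatives). Gcg, Sst, Chga, Chgb and Scg2 of this list are also islet genes, and Ins2, an islet marker, was at 0 FPKM in model and 0.762 in WMW-H. Mitochondrially encoded genes rose in 11 of 13 cases (adjusted p = 7.52e-07; adjusted p = 0.199 with an estimated correlation), mt-Co1 from 12480 ± 118 to 24540 ± 2219 FPKM, with WMW-H replicate 3 highest at 28480.

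Also called, but not with an estimated correlation, were xenobiotic and steroid metabolism genes (11 of 14 higher; adjusted p = 0.0846 with an estimated correlation) and tight junction genes (12 of 16 lower; adjusted p = 0.0846 with an estimated correlation). Squamous epithelium genes (5 of 5 lower; adjusted p = 0.0783 with an estimated correlation) and glycolysis and hypoxia genes (14 of 17 lower; adjusted p = 0.124 with an estimated correlation) behaved likewise. The tight junction call was also lost with size factors (adjusted p = 0.0589) and the replicate block (0.0543). Camera called 6 lists higher and 8 lower, and 8 of the 14 kept their call with an estimated correlation. Of 100 splits of the 10 libraries, 14 called as many lists, the real split included. Member counts adjusted over the list alone were equal for 38 of 40 lists, with 1 more plasma cell gene higher and 1 more endothelium gene lower.

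The largest rises in WMW-H against model were regenerating islet-derived genes, secreted lectins made by pancreas and gut. Reg3a was at 200 ± 10.6 FPKM in WMW-H, 1.504 ± 0.45 in model and 1.99 ± 0.25 in control. Reg2 was at 634 ± 44.5 FPKM in WMW-H and 20.4 ± 1.63 in model, and Reg3b at 764 ± 52.7 and 146 ± 3.42. Reg3d, Reg1 and the amylases Amy2a1 to Amy2a5 completed the 10. The 10 largest falls were all male accessory gland genes, such as Svs5, to 1.01 ± 0.88 FPKM, and Tgm4, from 72.7 ± 2.16 to 0.332 ± 0.20 FPKM.

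WMW-H was compared with control to ask what differed from untreated colon. Wnt targets, mast cell, macrophage and matrix genes were above control, and MHC class II, cytotoxic lymphocyte, B cell, plasma cell and adipocyte genes were below it. At least 2-fold changes were called in 221 genes that were higher and 118 that were lower. Without a fold limit, 4570 genes were higher and 3116 lower, with a median change of 1.23-fold, and groups did not overlap for 42.3% of genes (0.79% by chance). Higher genes made 59.5% of calls as deposited, 48% after quantile normalization and 49.6% without pancreas and accessory gland genes.

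Of 22 Wnt targets, 20 were higher (relative median 0.69, camera adjusted p = 6.02e-10). Mmp7 was at 97.2 ± 3.81 FPKM against 1.92 ± 0.21, Notum at 14.1 ± 0.93 against 0.157 ± 0.041 and Wif1 at 25.5 ± 1.62 against 1.246 ± 0.31. Mast cell genes were higher in 6 of 7 cases (adjusted p = 7.64e-05), Mcpt1 at 41.0 ± 2.11 FPKM. Macrophage and monocyte genes were higher in 13 of 14 cases (adjusted p = 0.000106), with Lyz2 at 270 ± 8.62 against 127 ± 5.10 FPKM, and Cd163 lower by a log2 change of -0.37. The matrix list was higher in 13 of 15 cases (adjusted p = 8.4e-08), Fn1 and Col1a1 by 1.00 and 1.11, with Postn at -0.16.

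All 10 MHC class II genes were lower (relative median -1.16, camera adjusted p = 6.02e-10), Cd74 at 398 ± 10.9 FPKM and H2-Aa at 168 ± 4.25 FPKM. All 6 cytotoxic lymphocyte genes were lower (adjusted p = 6.3e-05), Ccl5 at 8.15 ± 0.96 FPKM. Among B cell genes, 6 of 7 were lower (adjusted p = 0.000189), with Cd79a at 7.59 ± 0.59 against 17.0 ± 1.55 FPKM. Plasma cell genes were lower in 8 of 12 cases (adjusted p = 0.000417): Igha was at 2539 ± 98.7 against 5016 ± 58.4 FPKM and Ighg2c at 51.7 ± 2.29 against 259 ± 4.88 FPKM, while Prdm1 was higher by 0.46. All 9 adipocyte genes were lower (adjusted p = 2.85e-08), Cfd at 45.8 ± 5.30 against 140 ± 6.43 FPKM. Type I interferon genes were lower in 12 of 14 cases (relative median -0.69, adjusted p = 5.15e-09) and interferon gamma genes in 15 of 17 (adjusted p = 6.02e-10).

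Also higher than control as sets were neutrophil (5 of 6 genes, camera adjusted p = 0.0038), inflammatory cytokine (9 of 11, 0.0027), fetal-like and regenerating epithelium (9 of 10, 4.18e-05) and endothelium genes (9 of 11, 0.02). Also lower were goblet cell (9 of 12, 8.51e-05), absorptive colonocyte (13 of 18, 7.03e-05), tuft cell (5 of 6, 0.0206), T cell (7 of 12, 0.00511), enteric neuron and glia (8 of 12, 0.00384) and circadian clock genes (8 of 12, 0.00152). Calls lost with an estimated correlation were mitochondrially encoded (11 of 13 higher; adjusted p = 0.253 with an estimated correlation), ribosomal protein (12 of 15 higher; adjusted p = 0.249 with an estimated correlation) and myeloid suppression genes (4 of 7 higher; adjusted p = 0.109 with an estimated correlation). So were those of squamous epithelium (5 of 5 higher; adjusted p = 0.0707 with an estimated correlation) and epithelial antimicrobial defence (7 of 11 higher; adjusted p = 0.287 with an estimated correlation). The direction of the squamous epithelium genes against control was again largely fixed by the filter. Nuclear oxidative phosphorylation (9 of 14 lower; adjusted p = 0.137 with an estimated correlation) and immediate early and heat shock genes (9 of 13 lower; adjusted p = 0.0652 with an estimated correlation) lost theirs too. All lists set as checks for other tissue, handling, RNA quality or time of day were called here as well. Such differences cannot be told apart from the groups. Klk1 and Zg16 of the goblet list are made by the pancreas too, whose genes were lower in 30 of 36 cases. Quantile normalization lost the goblet cell (adjusted p = 0.0627, the call being kept in the other 22 of 23 settings) and squamous epithelium calls (0.117). The myeloid suppression call was lost without WMW-H replicate 3 (adjusted p = 0.059), and the antimicrobial defence call was kept in 14 of 23 settings, with adjusted p up to 0.0697.

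Camera called 13 lists higher and 16 lower, and 21 of the 29 kept their call with an estimated correlation. Member counts adjusted over the list alone were equal for 38 of 40 lists, with 1 more Wnt target and 1 more type I interferon gene lower. The largest rises included Reg3a, Mmp7, Lyz1, Reg2, Defa3, Defa24, Notum and Wif1, besides Clca4b, a chloride channel regulator, at 59.8 ± 2.66 against 3.76 ± 0.47 FPKM, and the acute phase gene Saa3, at 40.0 ± 3.40 against 2.88 ± 0.88 FPKM. The largest falls were Iglc1, Mptx1, Pla2g4c, Ighg2c and Retnla, the uridine phosphorylase gene Upp1, at 41.5 ± 2.33 against 170 ± 9.28 FPKM, and the pancreatic genes Pla2g1b, Try4, Ins2 and Ctrl.

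Whether WMW-H moved genes back towards control was read from changes in both directions. Of the 537 genes at least 2-fold higher in model, 483 were lower in WMW-H than in model and 16 higher, and 308 lay nearer to control than to model in WMW-H, with a median return of 55.5%. Of the 247 genes at least 2-fold lower in model, 204 rose in WMW-H and 12 fell, 110 lay nearer to control, and the median return was 44.1%. The doubled and halved genes held 13 accessory gland genes, all lower again in WMW-H, and 33 pancreatic genes, of which 32 rose. Without these, 470 of 524 genes were lower in WMW-H and 295 nearer to control, with a median return of 54.9%, and 172 of 214 were higher and 98 nearer, with 45.2%. Only genes of the pancreas and accessory gland lists were left out. Any other transcripts from those organs would remain and could look like a return. Over all calls, 3951 of 5881 genes higher in model were lower in WMW-H, where independent lists of these sizes would share 2407. In the other direction, 1694 of 2658 lower genes were higher in WMW-H, where independent lists would share 689. These independent-list values leave out that the model libraries are in both comparisons.

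The model libraries enter both comparisons with opposite sign, which makes the changes correlate negatively without any effect. Among genes called in model versus control, 81.8% changed sign in WMW-H versus model, which says little alone. Genes with an unadjusted p under 0.05 changed sign in 81.2% of cases, against 89.3% (86.3% to 91.5%) in 100 simulations of unchanged groups. Over all genes the share was 74.1%, against 66.6% (65.6% to 67.5%). Across genes, which are not independent replicates, Pearson r was -0.743 and the covariance -0.216, against -0.499 and -0.00312 in 100 simulations of unchanged groups. With the model libraries split so that no library was shared, r lay between -0.729 and -0.718 and the covariance between -0.213 and -0.211. Fitted with these 20 splits, 60.4% to 67% of the higher genes were lower in WMW-H and 55.7% to 63% of the lower genes higher, and 80.5% to 82.7% of called genes changed sign. The shared genes numbered 3265 to 3388 and 1357 to 1420, where independent lists would share 1903 to 1949 and 517 to 533. Median returns were 54.4% to 55.8% for doubled genes, of which 54.9% to 57.5% lay nearer to control, and 42.4% to 47.3% for halved genes, of which 43.8% to 47.1% did. Without the listed pancreas and accessory gland genes, r was -0.706. If the libraries of a group came from 1 RNA pool, the split does not remove what is particular to that pool.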

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

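The comparisons of immunoglobulin segments matched on fragments and across groups, the test for smoothed values, both tests on accessory gland genes and the paralog test on Paneth cell genes were chosen after the results were seen. The test on small-intestinal genes was set after the Paneth cell genes had been seen and before its own genes were seen in model versus control, but the fall of Fabp6 in WMW-H versus control was known by then. The remaining tests were set before. In 612 groups of 5 values, 50 held a library whose gap to its nearest neighbour exceeded 0.71 of the range, which is 8.2% where chance gives about 5%. WMW-H replicate 3 accounted for 16 of them, and no other library for more than 4.

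In WMW-H replicate 3, mitochondrially encoded genes lay above the other 4 libraries: mt-Cytb at 5414 FPKM (gap ratio 0.922), mt-Co1 at 28480 FPKM (0.879), mt-Co3 at 8376 FPKM (0.746) and the list mean (0.851). Also above were Chgb (117.7 FPKM, 0.746), Dcn (119.3, 0.756), Guca2a (1456, 0.778), Klk1 (1503, 0.75) and the smooth muscle list (0.823). Below lay Col1a1 (38.8 FPKM, 0.738), Igha (2366, 0.794), Jchain (335.1, 0.865), Reg3b (673.6, 0.716) and the lists of fatty acid oxidation (0.747), nuclear oxidative phosphorylation (0.856) and xenobiotic and steroid metabolism (0.775). Among other WMW-H libraries, Junb (0.727) and Slc7a5 (0.739) stood high in replicate 1, Tnf (0.74) and the Wnt target list (0.713) stood high in replicate 5, and Nkd1 in replicate 2 (0.855) and Nkg7 in replicate 4 (0.744) stood low.

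Among model libraries, Fn1 stood high in replicate 1 (0.771), where the enteric neuron and glia (0.794) and type I interferon lists (0.777) stood low. Igtp (0.888), Pou2af1 (0.724) and Sp5 (0.84) stood high in replicate 2. In replicate 4, Csf3r stood high (0.833) and Clu (0.722), Cxcl5 (0.739) and the interferon gamma list (0.868) low. In replicate 5, Irgm2 stood high (0.884) and Dcn (0.763), Hspa1b (0.848) and the fibroblast and matrix list (0.865) low.

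Among control libraries, Tgm4 (0.711), Ubd (0.734) and Zg16 (0.847) stood low in replicate 1, and the regulatory T cell and checkpoint list high (0.75). In replicate 2, Ccl5 (0.793) and the nuclear oxidative phosphorylation list (0.764) stood high, and Il4i1 (0.728) and the tight junction list (0.829) low. In replicate 4, Dcn (0.803), Ifit1 (0.846) and the type I interferon list (0.824) stood high and Igtp low (0.762). In replicate 5, Gzmb stood high (0.869).

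Libraries of 1 group differed little: above 2000 fragments, the variation beyond sampling was 1.71% in control, 1.67% in model and 3.76% in WMW-H, and shares of other organs' genes ran close too (accessory gland 0.582% to 0.608% in model, pancreas 6.934% to 7.001% in control), which bears on a shared pool, but no bound had been set before these values were seen. Immunoglobulin variable segments, which separate animals rearrange on their own, varied 2.64, 2.6 and 1.94 times as much as genes of the same FPKM in control, model and WMW-H, between the bounds of 1.5 for a shared pool and 3 for separate repertoires. As the segments are short, they were then matched on fragments, which gave 1.61 (1.36 to 1.84) in control, 1.55 (1.41 to 1.67) in model and 1.28 (1.16 to 1.41) in WMW-H, the last under the pool bound. After that they were compared between and within groups (4.22, interval 3.77 to 4.72), and none of these 3 tries on the same data met its bounds in all groups. Smoothed values are argued against, since the lowest dispersion was 1.84 times that of sampling. None of the 3 tries reached the bounds set for separate repertoires. Missing those bounds does not argue against separate animals, since the tries did not meet the opposite bounds in all groups. The last try also takes in any change of these segments between groups. The close shares of other organs' genes show that libraries of a group held nearly equal amounts of that RNA. With no bound set beforehand, they bear on the question without deciding it. The bound for a shared pool was met in WMW-H alone, with segments matched on fragments, so 1 RNA pool per group was not shown either.

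Male accessory gland genes were high in the model libraries and near 0 in the others. Of the 15 genes, 13 were at least doubled and higher in 5 of 5 model libraries. The list made 4e-04% of the FPKM total in control, which shows only that untreated colon held little of it. Reads shared among the Svs paralogs are argued against, since 4 of 6 genes outside that family were doubled as well. RNA of these glands in the model samples is a candidate explanation, as a hypothesis made from these data. The list made 6e-04% in WMW-H, whose animals were model animals too. For the listed genes, this argues against an effect of AOM/DSS in colon that persists under WMW-H. An effect of AOM/DSS that WMW-H undid stays open as untested.

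Paneth cell genes were high in the model libraries, at 0.293% of the FPKM total, and lower in WMW-H. Tissue of the small intestine, where Paneth cells reside, is argued against, since 11 tested small-intestinal enterocyte genes had a median log2 change of -0.655 (bootstrap -1.416 to 0.031; -0.627 without Fabp6, bootstrap -1.036 to 0.1), with 8 lower and 2 higher. Rbp2 (11.7 FPKM in control, 29.8 in model) and Cubn (0.700 and 1.703) were the higher ones, while Fabp6 was at 3.41 and 0.273 FPKM and Sis at 1.98 and 0.115. Several of the 11 were well expressed in control colon, such as Slc5a1 at 44.6 FPKM, so their fall could hide a small admixture, which is not excluded. Members under 1 FPKM were not tested. Of these, Apoa1 and Fabp1 were at 0.794 and 0.380 FPKM in control and 0.563 and 0.344 in model. Apoa4, Apoc3, Lct, Mttp and Treh had higher means in model, all under 1 FPKM. Reads shared among defensin paralogs are argued against as the whole cause, since 2 of 2 genes outside that family, Lyz1 and Mmp7, were doubled as well; Mmp7 is also a Wnt target. Paneth-like cells in the model tissue are a possible explanation, as a hypothesis made from these data and not tested.

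Over 100 of the 126 splits of 10 libraries, a chance labelling of the libraries was argued against for the gene counts. The splits exchange single libraries, so if those of a group share 1 pool or tissue, chance differences between pools are not excluded. Every other split also mixes the groups, which widens the spread within them and tends to lower its calls. The real split gave 8539 genes for model versus control against at most 5 in any other, 8633 against 345 for WMW-H versus model and 7686 against 529 for WMW-H versus control, and 1 of the 100 splits, the real one, reached each count. For gene lists, 4 of 100 splits called as many lists as the real 29 in model versus control, with a median of 10 and up to 30 in the others. In WMW-H versus control, 1 of 100 did, with 29 lists against a median of 7 and up to 28. Fewer than 5% of splits reached the count in both, which argues against a chance labelling for the count, with the same limits, but not for single lists. In WMW-H versus model, 14 of 100 splits called as many as the real 14 lists, with a median of 4 and up to 16, so chance was not excluded for that count.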

How the results depend on the processing

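The fit without pancreas and accessory gland genes was chosen after the data were seen. Over 26 results, 682 values under alternatives were computed: 647 kept their direction and side of the threshold or moved within the limits set, 31 moved, 4 came to pass the threshold and 0 reversed. Of 5968 values for 218 named genes and comparisons, 5949 stayed the same, 18 no longer passed, 1 came to pass and 0 reversed. Where no cause is named, the cause was not tested.

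Quantile normalization gave 3765 genes higher and 4167 lower in model versus control. A limit of at least a doubling or halving left by construction 537 higher and 247 lower, 108 and 249 for WMW-H versus model, and 221 and 118 for WMW-H versus control. With an estimated inter-gene correlation, 4 lists were lower in WMW-H versus model and 8 higher in WMW-H versus control. By fry, which tests another question, 13 lists were higher and 21 lower in WMW-H versus model.

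The mean log2 change of AHR and its targets in WMW-H versus control (0.07, permutation p = 0.0714) came to pass with no filter (0.063, p = 0.00794), a mean of at least 5 FPKM (0.127, p = 0.00794) and TPM (0.128, p = 0.0159). Leaving out each library gave 0.053 to 0.092, which passed without WMW-H replicate 3 (permutation p = 0.0238). The share of called genes with opposite sign, 81.8%, was 82.6% with no filter, 80.9% at a mean of at least 5 FPKM, 83.2% with TPM, 80.4% with size factors, 81.3% after quantile normalization, 82.4% without pancreas and accessory gland genes, 80.5% to 82.7% with model libraries split, and 81% to 82.5% on leaving out each library. The correlation of changes, -0.743, was -0.706 without those genes, -0.729 to -0.718 with model libraries split and -0.746 to -0.703 on leaving out each library. By construction, leaving out a model library drops genes seen only in the 5 model libraries.

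The replicate numbers did not pair the samples: same-numbered libraries had correlations of -0.047 to 0.03, and 2 of 15 correlated best with their own number. With the replicate block, 5849 genes were higher and 2636 lower in model versus control, 3323 and 5251 in WMW-H versus model, and 4525 and 3073 in WMW-H versus control. With the block, camera called 14 lists higher and 16 lower, 6 and 7, and 12 and 16 in these comparisons. Of simulated genes with the smallest fold change, 76%, 70% and 70% were recovered in the 3 comparisons. Recovery by expression level was not tested.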

Other observations

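Several gene groups moved gene by gene in WMW-H against model without the list differing from other genes. All 6 neutrophil genes were lower (camera adjusted p = 0.078; passed in 1 of 23 alternative settings, at 0.0431), as were 6 of 7 mast cell genes (0.112) and 9 of 12 p53 target genes, with 1 higher (0.078). All 3 tested dendritic cell genes were higher in model than in control and lower in WMW-H than in model, and 0 of them differed between WMW-H and control. Of 25 cell cycle genes, 13 were lower and 6 higher in WMW-H against model (0.599).

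The epithelial antimicrobial defence list went both ways. In model versus control, 6 of 11 genes were higher and 4 lower, and in WMW-H versus model 6 were higher and 5 lower. Reg3b was at 178 ± 5.71 FPKM in control, 146 ± 3.42 in model and 764 ± 52.7 in WMW-H (SD, n = 5). Reg2, which the pancreas list holds, was at 23.4 ± 1.35, 20.4 ± 1.63 and 634 ± 44.5 FPKM, while pancreatic genes together went from 6.97% of the FPKM total in control to 1.59% in model and 3.29% in WMW-H.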
